A study of Mus musculus with 2 samples.

How the data were processed

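MicroRNA sequencing measured small RNA of the adrenal gland of adult male mice. The strain is given as 5xFAD/CAST, which joins the name of a transgenic Alzheimer's disease model with that of a wild-derived inbred strain. Per the labels, the mice were 8 to 10 months old and the RNA was below 30 nucleotides. There were 2 libraries, labelled biological replicates 1 and 2 of 1 group. Their sample records differed and their donor record was the same, so the labels do not say whether 2 animals were used. The spread between the replicates may therefore be partly technical. The labels do not give the transgene status of these animals.

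The authors deposited, for each library, a table of read counts per annotated miRNA gene in 3 columns, for both strands together, for the strand of the gene and for the opposite strand. Per the text deposited beside each table, the annotation was GENCODE M21 on assembly mm10, and each table came from 1 library. The layout, with lines for unmapped, multimapping, unassigned and ambiguous reads, is that of the gene counts written by the aligner STAR. The aligner used, its version, adapter trimming and mismatch settings are not given in the sources used here. The strand columns carry no header and were identified from this layout and from their totals. The column taken as sense held 88.6% and 91.8% of the stranded assignments of replicates 1 and 2. Nearly all of the rest lay in miRNA genes overlapped by one on the other strand, where both columns count the same reads. Opposite-strand reads in genes without such a partner numbered 95 and 36.

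This processing shapes the values. A count belongs to a hairpin gene and not to its 5' or 3' arm. Multimapping reads were assigned to no gene, so genes with near-identical copies are undercounted. In the column for both strands, a gene overlapped by a miRNA gene on the other strand loses its reads as ambiguous, so sense counts were used throughout. Reads were compared with a reference of another strain, and a CAST variant inside a mature sequence could lower the count of that gene. The tables give no molecular identifiers, so intervals and floors below cover counting error only.

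All gene identifiers were found in GENCODE M21, which supplied names, hairpin sequences, positions on GRCm38 (mm10) and host genes. CPM values, the sense count scaled to a total of 1000000 sense miRNA reads per library, were computed from totals of 6783227 in replicate 1 and 3084602 in replicate 2. The mapping lines were left out of these totals. For a gene without near-identical copies, a count of 0 allows up to 3 reads, which is 0.442 CPM in replicate 1 and 0.973 CPM in replicate 2. Shares are given with Wilson 95% intervals where they belong to 1 library. A gene was detected above 2 CPM in both libraries.

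With 1 group there was no contrast and no test across animals. The CPM of 2 genes was called different only when both libraries ordered them alike and both gaps exceeded the replicate difference of either gene. This rule covers the spread between the replicates only. A capture bias shared by both libraries would pass it, so it orders CPM values and not molecules. Agreement was the Pearson and Spearman correlation across genes of log2(CPM + 1) for the 280 genes of mean CPM of at least 10. The biological coefficient of variation came from edgeR with TMM factors and an intercept alone. Replicate differences were log2(CPM + 1) of replicate 2 minus replicate 1. They were called at a Benjamini-Hochberg adjusted p under 0.05 in a two-sided Fisher's exact test on reads and an absolute log2 difference of at least 1. This test compares 2 libraries, not conditions or animals, and takes reads as independent molecules, so a low p shows a difference beyond read counting only. The median log2 difference of each gene list with at least 3 members of 10 CPM was placed among 10000 random lists matched on mean expression. Cluster mates were compared with 100000 permutations.

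The lists of cell types, pathways, families and genomic clusters and the rule for named genes were fixed before the data were examined. The rule names the 20 most abundant genes and up to 4 members of each list. It also names the 5 highest and 5 lowest replicate differences among genes of mean CPM of at least 100, and the highest and lowest member of each cluster. Older symbols in the lists, such as Mir146a for Mir146, were matched to the annotation by synonym, and this step was added after counts had been seen. Genes sharing 20 bases with another hairpin numbered 1084 in the annotation and 68 among the 280 genes.

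The steps were tested on simulated data. A simulated coefficient of variation of 30% was estimated as 30.9% over 280 genes. Of 275 simulated genes compared between the replicates, Fisher's exact test called 37 of 38 changed by 1.5 in log2, 44 of 44 changed by 2, and 1 of 193 unchanged. These simulated libraries held counting error only. They do not show how often the test calls unchanged genes when replicates vary beyond counting. The cluster permutation test gave p = 0.0136 when clusters were shifted together, and 4 of 40 tests without a shift fell under 0.05. The shifted case was a single draw with shifts as large as the noise of single genes, so smaller shifts were not tried. Alternatives were the column for both strands, TMM and DESeq2 scaling, other filters, pseudocounts and denominators, the removal of genes with copies, and leaving out each replicate. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.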

Results

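MicroRNA sequencing profiled the adrenal gland of adult male 5xFAD/CAST mice in 2 replicates of 1 group. The tables held 13209343 reads for replicate 1 and 6482170 for replicate 2. Sense reads of miRNA genes made up 51.4% (Wilson 95% interval 51.3 to 51.4) and 47.6% (47.5 to 47.6) of them. Multimapping reads made up 30.3% and 32.1%, unmapped reads 14.7% and 16.5%, and uniquely mapped reads outside miRNA genes 3.61% and 3.72%. With no second group, the data describe which miRNA genes were abundant in this tissue and how closely the replicates matched.

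By mean CPM, the adrenal profile was led by Mirlet7g, Mir10a, Mir126a, Mirlet7b and Mir375. Mirlet7g, a member of the let-7 family that is abundant in differentiated tissues, reached 117872 ± 10071 CPM (SD, n = 2). Mir10a, which lies in the Hoxb region, reached 73755 ± 10219 CPM, and the endothelial Mir126a reached 72565 ± 28349 CPM. Mirlet7b reached 71944 ± 12351 CPM, and Mir375, known from neuroendocrine cells, 70580 ± 16777 CPM. Mirlet7g exceeded 15 of the 16 other genes of the top 20 without near-identical copies by more than the replicate spread. Mir126a was the exception, at 92610 CPM in replicate 1 and 52519 CPM in replicate 2. Mir10a, Mir126a and Mir375 were not above Mir23a, the sixth by mean, beyond the replicate spread, and the count of Mir23a is a lower limit.

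Mirlet7g (ENSMUSG00000065440.1) lies in an intron of Wdr82 on chromosome 9 at 106178840 to 106178927 of GRCm38. Mir10a (ENSMUSG00000065519.1) lies on chromosome 11 at 96317165 to 96317274, outside other annotated genes of its strand. Mir126a (ENSMUSG00000065540.1) overlaps an exon of Egfl7 on chromosome 2 at 26591357 to 26591429. Mirlet7b (ENSMUSG00000065564.1) overlaps an exon of the noncoding gene Lncppara on chromosome 15 at 85707319 to 85707403. Mir375 (ENSMUSG00000065616.3) lies on the minus strand of chromosome 1 at 74900658 to 74900721, outside other annotated genes of its strand.

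The next genes by mean CPM were Mir23a at 48684 ± 14212, Mirlet7i at 40266 ± 2134, Mir23b at 40041 ± 10180, Mir26b at 31702 ± 17891 and Mir99a at 28815 ± 3650 CPM. Mirlet7d, Mir143, Mir127, Mir139, Mir10b, Mir322, Mir379, Mir411, Mir652 and Mirlet7e completed the 20, between 28598 ± 2273 CPM for Mirlet7d and 12164 ± 1741 CPM for Mirlet7e. Mir139, in an intron of Pde2a, was at 21469 ± 9437 CPM, and Mir10b, in an intron of Hoxd4, at 21218 ± 9307 CPM. Mir23a and Mir23b share 20 bases, as do Mir411 and Mir758, so reads common to each pair were not counted for either, and the ranks of Mir23a, Mir23b and Mir411 are uncertain. Of the 136 pairs among the other 17 genes, 73 were ordered beyond the replicate spread.

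**Figure D1:**
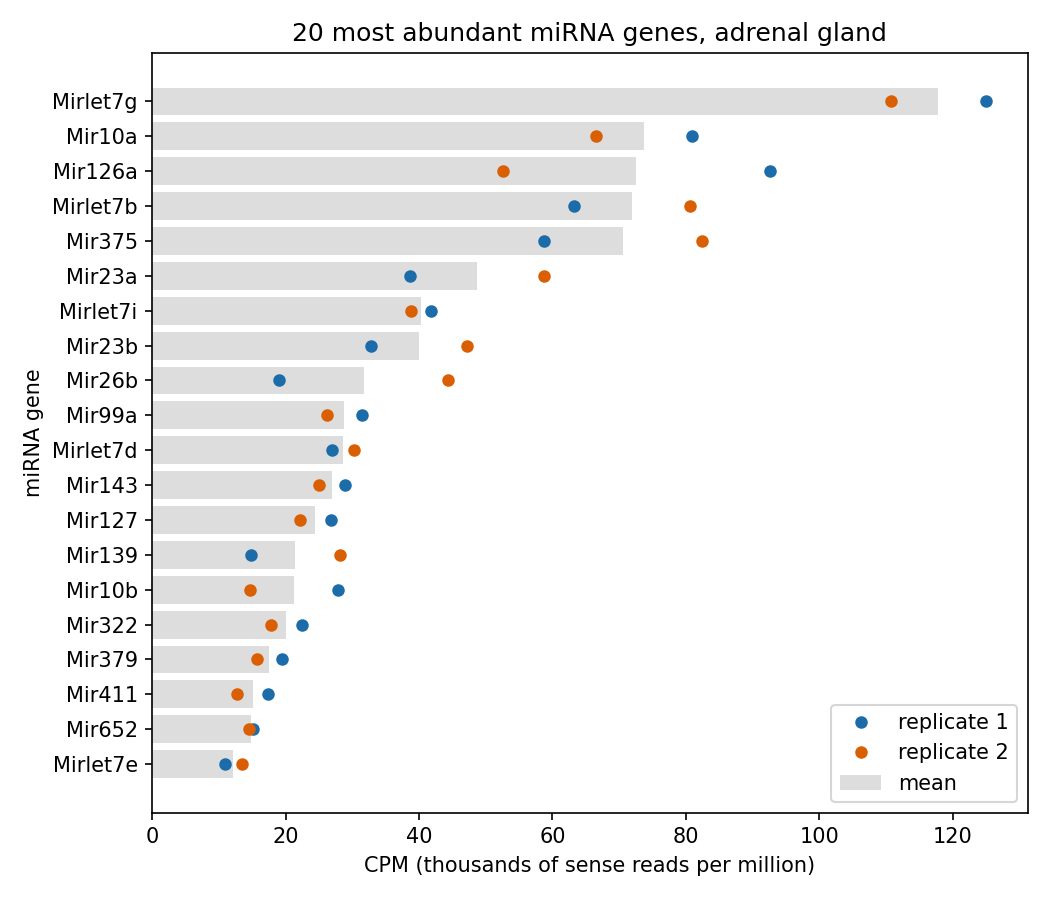
CPM (axis in units of 1000) of the 20 most abundant miRNA genes, with a grey bar for the mean of 2 replicates and a point for each replicate. Mirlet7g has the highest mean, 117872 CPM, and the points of Mir126a and Mir26b lie far apart.

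Uniquely assigned reads were concentrated in few genes. The 10 most abundant genes held 58.4% (58.4 to 58.5) of these miRNA reads in replicate 1 and 60.8% (60.8 to 60.9) in replicate 2. The mean was 59.6% ± 1.70 (SD, n = 2). The top 20 held 79.9% ± 0.541 and the top 50 held 93.4% ± 0.0436. Of the annotated genes, 334 were detected above 2 CPM in both replicates and 173 had a mean of at least 100 CPM. Multimapping reads, 30.3% and 32.1% of all reads in replicates 1 and 2, were assigned to no gene and could change these values.

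Among families, let-7 with Mir98 took the largest share, 28.2% ± 0.331 of miRNA reads (n = 2). The mir-10 family held 9.50% ± 1.95, the mir-125, mir-99 and mir-100 genes 4.70% ± 0.362, and the mir-26 family 3.17% ± 1.79. The mir-30 family held 1.76% ± 0.0761, with Mir30d at 6894 ± 351 CPM and Mir30a at 6490 ± 361 CPM. The mir-29 family held 1.03% ± 0.0933, led by Mir29a at 8682 ± 129 CPM, while mir-181 held 0.189% ± 0.00576 and the mir-148 and mir-152 genes 0.0532% ± 0.0262. Of the 13 let-7 genes of at least 10 CPM, 0 differed between the replicates by the call used here. Of the 14 let-7 genes, 6 share 20 bases with another hairpin, and their counts are lower limits. The same holds for 2 of 3 mir-26 genes and 2 of 6 mir-125, mir-99 and mir-100 genes. It also holds for 2 of 7 mir-30, 3 of 4 mir-29 and 4 of 6 mir-181 genes. The family shares and their order therefore describe uniquely assigned reads only.

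Markers of endothelium, neuroendocrine cells and smooth muscle were the most abundant of the cell type lists. The endothelial list held 7.64% ± 2.85 of miRNA reads, almost all from Mir126a, with Mir100 at 3362 ± 212 CPM and Mir92-1 at 436 ± 37.7 CPM. The neuroendocrine list held 7.58% ± 1.69, from Mir375 and from Mir7b at 4479 ± 79.1 CPM. The smooth muscle and pericyte list held 2.76% ± 0.273, with Mir143 at 26930 ± 2717 CPM and Mir145a at 631 ± 15.1 CPM. With the column for both strands the endothelial share was 0.427%, because Mir126a and the opposite-strand Mir126b overlap.

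Lists of other cell types held smaller shares. The lists hold from 1 to 18 genes and cell types were not measured apart. Their shares therefore do not show how much each cell type contributed. The erythroid list held 0.385% ± 0.241, mainly Mir451a at 3650 ± 2405 CPM, and the adipose list 0.359% ± 0.0219, mainly Mir378a at 3342 ± 282 CPM. With the column for both strands these shares were 0.0212% and 0.0281%, since Mir451a and Mir378a overlap opposite-strand miRNA genes, and Mir378a also shares 20 bases with Mir378c. Of the 5 erythroid genes, 2 others than Mir451a share 20 bases with another hairpin, so their counts are lower limits. The leukocyte list held 0.181% ± 0.0295, led by Mir146 at 1162 ± 354 CPM, which shares 20 bases with Mir146b, and 0.0751% without genes that share 20 bases. It also held Mir142 at 266 ± 23.3 CPM, Mir150 at 176 ± 20.5 CPM and Mir155 at 154 ± 9.68 CPM. The neuronal list held 0.133% ± 0.0287, with Mir137 at 885 ± 244 CPM, and 17 of its 18 genes share 20 bases with another hairpin. The fibroblast list held 0.0956% ± 0.0507, the epithelial list 0.0504% ± 0.0103 and the kidney list 0.0320% ± 0.00162, or 0.0106% without genes that share 20 bases. Of the 5 fibroblast genes, 3 share 20 bases with another hairpin, and their counts are lower limits. The epithelial list was led by Mir203 at 464 ± 111 CPM and the kidney list by Mir196a-2 at 197 ± 10.3 CPM, a gene that shares 20 bases with Mir196a-1.

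By reads assigned to a gene, markers of neighbouring or unrelated organs were close to the detection floor or low. The liver marker Mir122 held 0.0257% of reads in replicate 1 and 0.00577% in replicate 2. The gonad list held 0.00209% ± 0.00026, and 12 of its 13 genes had 0 reads in both replicates, with Mir202 at 20.9 ± 2.60 CPM. The striated muscle list held 0.000483% ± 8.77e-05 and the acinar pancreas list 6.04e-05% ± 3.96e-05. Of the 9 striated muscle genes, 5 share 20 bases with another hairpin. Among these, Mir1a-1 and Mir133a-1 had 0 reads in both replicates. Multimapping reads were assigned to no gene, so a count of 0 sets no upper limit for them.

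**Figure D2:**
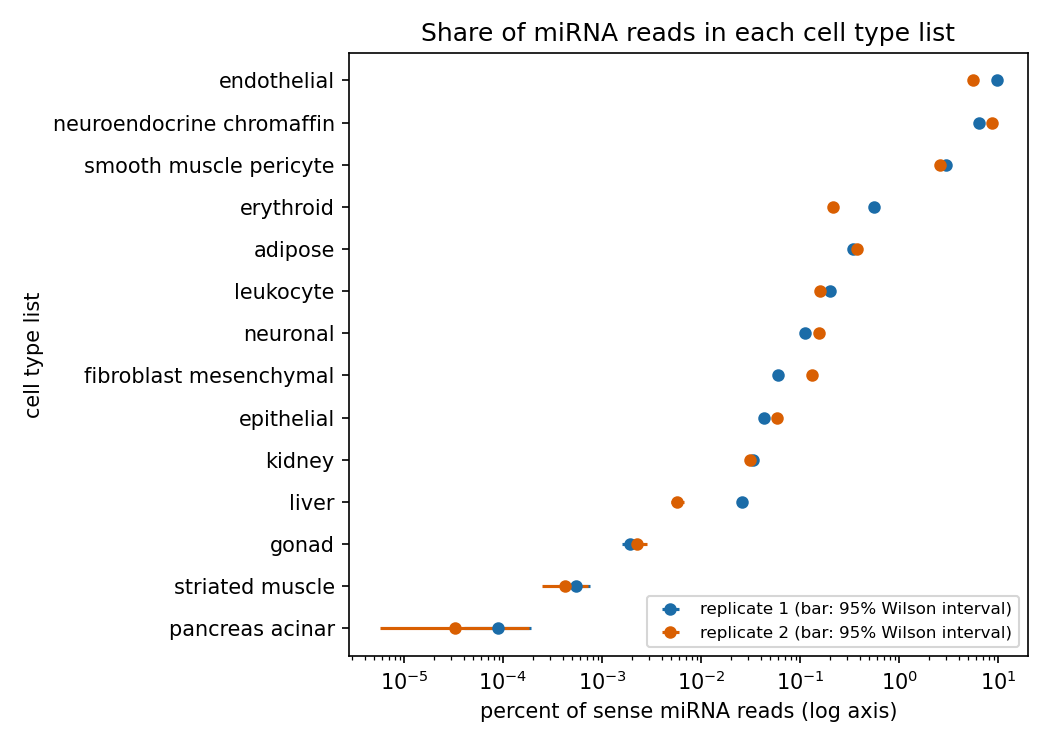
Percent of sense miRNA reads in each of the cell type lists on a log axis, with a point per replicate and bars for the Wilson 95% interval of counting error. The endothelial (7.64%) and neuroendocrine (7.58%) lists have the highest mean shares, and the acinar pancreas list the lowest (6.04e-05%).

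Genes of named pathways were present at moderate levels. The inflammation list held 0.450% ± 0.0285, led by Mir21a at 3128 ± 53.3 CPM, and the p53 list 0.276% ± 0.152, led by Mir34a at 2136 ± 1092 CPM. Genes listed as responsive to adrenocorticotropic hormone, the pituitary hormone that drives adrenal steroid output, held 0.260% ± 0.0624. They included Mir27a at 665 ± 94.8 CPM, Mir214 at 593 ± 336 CPM and Mir132 at 531 ± 23.7 CPM. Mir27a shares 20 bases with Mir27b. In all, 3 of these 12 genes and 2 of the 5 inflammation genes share 20 bases with another hairpin, and their counts are lower limits. Mir210, the hypoxia marker, was at 211 ± 41.1 CPM.

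The imprinted Dlk1-Dio3 region of chromosome 12 was broadly expressed. Its 56 listed miRNA genes, from 109563692 to 109747960, held 8.74% ± 1.05 of miRNA reads, and 47 of them reached a mean of 10 CPM. Of the 56, 9 share 20 bases with another hairpin, and their counts are lower limits. Mir127 was highest at 24415 ± 3300 CPM, followed by Mir379 at 17574 ± 2729, Mir411 at 15053 ± 3342 and Mir382 at 5997 ± 1860 CPM. Mir412 was the lowest of the 47 at 11.9 ± 0.580 CPM, so mean levels among these 47 spanned 2050-fold. The other 9 were lower, and 4 of them had 0 reads in both replicates. The imprinted Sfmbt2 cluster of chromosome 2 held 0.0528% ± 0.00702, with Mir467d at 228 ± 42.4 CPM. In this cluster, 67 of 69 genes share 20 bases with another and 60 had 0 reads in both replicates.

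**Figure D3:**
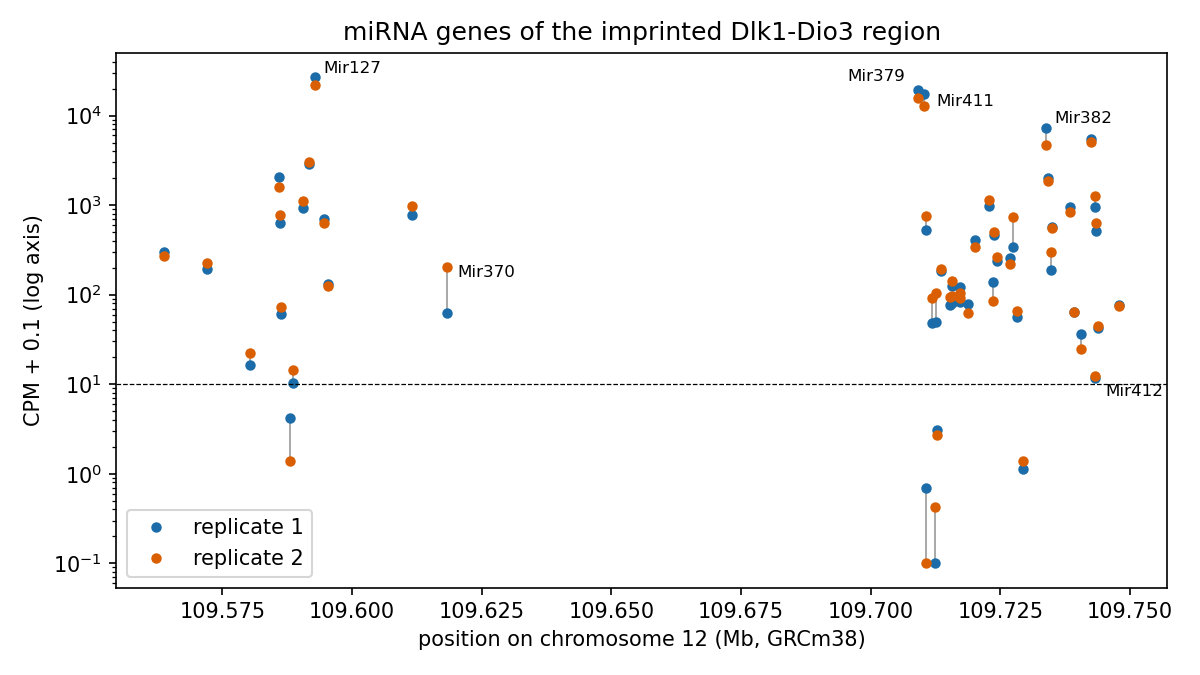
Level of the miRNA genes of the Dlk1-Dio3 region, as CPM + 0.1 on a log axis, against position on chromosome 12 of GRCm38 in Mb. A point is 1 replicate, a grey line joins the replicates of a gene, genes with 0 reads in both are left out, and the dashed line marks 10 CPM. Mir127, Mir379 and Mir411 stand highest, at mean values of 24415, 17574 and 15053 CPM.

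Members of smaller clusters, which are processed from shared transcripts, also stood at unequal CPM. These ratios include any capture bias shared by both libraries. Mir143 was 42.7-fold above Mir145a, with ratios of 44.9 and 40.3 in the replicates. Mir322 was 1950-fold above Mir450-2, although Mir450-2 shares 20 bases with Mir450-1. Mir191 was 12.3-fold above Mir425, and Mir93 was 7.46-fold above Mir25. By contrast, Mirlet7e was 1.90-fold above Mir125a. Mir15b stood 1.13-fold above Mir16-2, which shares 20 bases with Mir16-1, so its count is a lower limit and their order is uncertain.

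The replicates ranked miRNA genes alike, and a minority differed at least 2-fold. Mir31 differed most among genes of at least 100 CPM, at 1230 CPM in replicate 1 and 106 CPM in replicate 2 (log2 difference −3.53). Mir122 (−2.14), Mir107 (−2.10), Mir34c (−1.60) and the red cell marker Mir451a (−1.46) were also lower in replicate 2. Mir301 (2.00), Mir370 (1.70), Mir101a (1.49), Mir195a (1.26) and Mir214 (1.22) were higher. The adjusted p of Fisher's exact test was 1.9e-117 for Mir122 and 6.8e-180 for Mir301, and these tests compare the reads of 2 libraries only. Mir107 shares 20 bases with Mir103-1 and Mir103-2, and Mir101a with Mir101b.

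Across the 280 genes, Pearson's r was 0.979 (0.971 to 0.986 by bootstrap over genes) and Spearman's rho 0.972. Genes are not independent replicates. The biological coefficient of variation was 30.1%. Fisher's exact test gave an adjusted p under 0.05 for 69.3% of the genes, and 30 of them also differed at least 2-fold, 17 higher and 13 lower in replicate 2. The split depended on scaling, with 12 higher and 17 lower under TMM and 8 higher and 17 lower under DESeq2 size factors. The median log2 difference was 0.012 as scaled here, −0.089 under TMM and −0.12 under DESeq2 size factors. Among the 173 genes of at least 100 CPM, 127 lay within 0.5 in log2 and 19 were called.

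**Figure D4:**
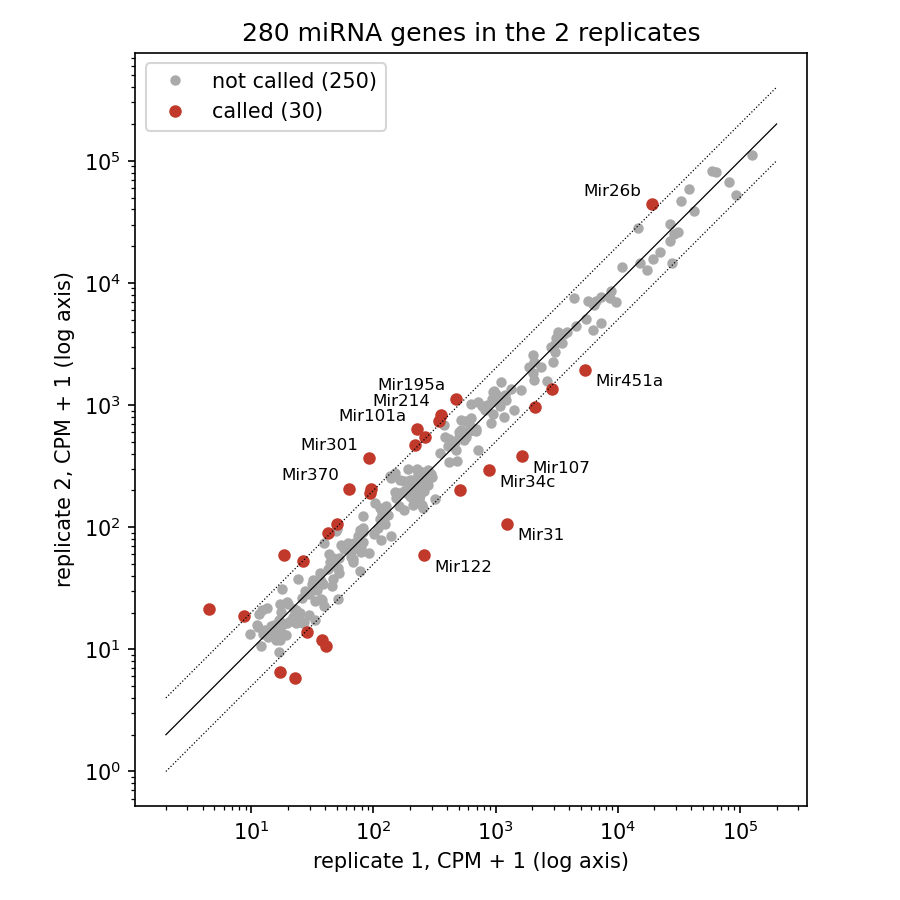
CPM + 1 of 280 miRNA genes in replicate 1 and replicate 2, both on log axes, with a solid line for equality and dotted lines for a 2-fold difference. Red points are the 30 genes called different between the libraries, among them Mir31 at 1230 and 106 CPM.

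As groups, 5 of the 29 lists tested had a median replicate difference outside the central 95% of matched random lists, with no adjustment over the 29. The mir-26 family was higher in replicate 2, with a median log2 difference of 1.22 (percentile 99.965), and Mir26b itself was called. Its other members, Mir26a-1 (2.24, called) and Mir26a-2 (0.82, not called), share 20 bases with each other and stood at 12.0 and 23.6 CPM. The random lists hold unrelated genes, so percentiles of family lists do not allow for members that vary together. This includes the p53 list, which holds only the related Mir34a, Mir34b and Mir34c. The fibroblast list had a median of 1.12 (98.51), the value of Mir152, with Mir214 and Mir152 higher and Mir199b lower. Mir199b stood at only 21.7 and 4.86 CPM in replicates 1 and 2. It is among the 3 of 5 fibroblast genes that share 20 bases with another hairpin, so its direction is uncertain. The mir-148 and mir-152 genes had a median of 1.11 (98.955), with Mir148a and Mir152 called. Mir152 is also in the fibroblast list, so these 2 results are not separate. The neuroendocrine list had a median of 0.49 (98.62), with 1 of 7 members called. The p53 list had a median of −1.09 (0.65), with Mir34a and Mir34c lower and Mir34b at −0.17. TMM and DESeq2 scaling shift all genes by nearly the same amount, so they left these 5 percentiles unchanged and are no check. Under DESeq2 size factors, Mir148a at 0.977 and Mir152 at 0.981 fell below the limit of 1 for a call. The fibroblast list lost its call with the column for both strands (percentile 97.225). Among genes of at least 100 CPM the neuroendocrine list lost its call (95.5), the other 4 had too few members to test, and the list of genes responsive to adrenocorticotropic hormone lay outside (98.69).

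Genes of one genomic cluster did not detectably differ together between the replicates. The mean absolute difference between cluster mates was 0.49 in log2 over 1159 pairs of 118 genes, against 0.51 for permuted values (two-sided permutation test, p = 0.707). Most of these pairs lay in the Dlk1-Dio3 region. Without the imprinted clusters, an unplanned alternative, 68 pairs of 66 genes gave 0.496 against 0.530 (permutation p = 0.514). Mir144 and Mir451a, from 1 transcript, had log2 differences of −0.028 and −1.46.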

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

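The comparison of cluster mates was planned, but its limits were written after its result had been seen, and the other tests in this part, with their limits and bins, were chosen after seeing the data. The design has 1 group, so no explanation by a difference between groups was tested.

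Some reads lay outside the main counts. Multimapping reads numbered 4001595 in replicate 1 and 2084009 in replicate 2, and the tables do not say which genes they came from. Opposite-strand reads in the 2138 genes without an annotated partner numbered 95 and 36, led by Mir203 with 12 and 5 and by Mir708 with 12 and 4.

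Sampling of reads or molecules alone would make the SD of log2 differences over the 280 genes fall with abundance, but the SD of genes of 1000 CPM or more was 0.822 of that of genes of 10 to 100 CPM (bootstrap 95% interval 0.580 to 1.13), beside 0.0956 for sampling, and 0.770 to 1.02 over all 5 choices of bins. A straight-line trend with hairpin GC content (Spearman's rho 0.19 across genes) was not the whole cause, because 27 of the 30 called genes kept a 2-fold difference once it was removed. Its slope was 0.107 in log2 per 10% GC, so its removal could cost only calls near the limit. GC was that of the whole hairpin, and a trend with GC of the mature arm was not tested. Changes of whole transcription units stay open, since cluster mates differed by 0.492 in log2 and permuted pairs by 0.511 (permutation p = 0.707). Members of a sequence family at distant loci differed by 0.465, against 0.627 for permuted pairs (permutation p = 0.0763), with permutation p from 0.00134 to 0.0310 under 4 other choices of families, weights or pairs, and 0.575 among pairs with at least 2 mismatches in every 20 bases. Neither like capture of similar sequences nor exchange of reads between near-identical members is shown or excluded by these values, and a difference between the animals or glands was not tested.

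Mir451a, an erythroid miRNA, was lower in replicate 2 by a log2 difference of −1.46. Less blood in replicate 2 would lower Mir144, from the same transcript, by a like amount if blood holds the 2 at a fixed ratio, which was not tested. Mir144 stood at −0.028 (exact 95% interval −0.17 to 0.11), which argues against less blood under that condition. Mir486, with only 96 and 39 reads, stood at −0.16 (−0.74 to 0.39) and adds little. Of the 5 erythroid genes, 2 share 20 bases with another hairpin. Mir451a and Mir144 do not, so the count of Mir486 may be a lower limit. Both intervals cover counting error only. What set Mir451a apart was not tested.

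In the column for both strands, 25 of the 279 genes with at least 100 sense reads lost them, among them Mir126a, Mirlet7e, Mir191 and Mir451a. That column sets reads of overlapping miRNA genes aside as ambiguous, 873915 in replicate 1 and 274367 in replicate 2. An annotated miRNA gene on the opposite strand was present for 25 of the 25 lost genes and for 0 of the 254 kept genes. These counts follow from that rule and are no separate test. The loss took 12.9% and 8.89% of sense reads in replicates 1 and 2.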

How the results depend on the processing

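Of the list shares under alternatives other than leaving out a replicate, 82 moved by less than 1 SD and 92 by more. Without genes that share 20 bases the kidney share was 0.0106%, the adipose share 0.0276% and that of both mir-23 clusters 0%. Among the main results, these moved. Detected genes numbered 549 at 1 read or more in both libraries. The top 10 share was 61.9% with the column for both strands and 55.5% of all uniquely mapped reads. The correlation was 0.989 without a filter and 0.967 at 100 CPM or more, where the range of levels differs. Calls numbered 50 without a filter and 19 at 100 CPM or more, since more or fewer genes were tested. The endothelial share was 0.427% with the column for both strands, which drops Mir126a. The let-7 share was 30.3% with that column, 18.6% without Mirlet7g and 31.8% without genes that share 20 bases. The Dlk1-Dio3 share was 9.92% without Mirlet7g. At 100 CPM or more, 1 of 17 lists lay outside the central 95%, the neuroendocrine list lost its call (95.5), and the mir-26, mir-148 and mir-152, fibroblast and p53 lists had too few members. With the column for both strands the fibroblast list lost its call (97.225), and the cause was not tested. The comparison of cluster mates reversed to 0.54 against 0.51 (permutation p = 0.637) with equal weight per cluster, an alternative added after seeing the data, and the cause was not tested. Leaving out each replicate gave 348 to 359 detected genes, top 10 shares of 58.4% to 60.8%, endothelial shares of 5.62% to 9.65%, let-7 shares of 28.0% to 28.5% and Dlk1-Dio3 shares of 8.00% to 9.49%. These are the single libraries, and a mean of 2 values moves by less than 1 SD by construction, so they are no check. Replicates 1 and 2 differed over 1.5-fold in the shares of the endothelial list and of mir-26 (1.91% and 4.44%), erythroid (0.556% and 0.215%), p53 (0.384% and 0.169%), fibroblast (0.0598% and 0.131%), mir-148 and mir-152 (0.0347% and 0.0717%), liver (0.0257% and 0.00577%) and acinar pancreas (8.85e-05% and 3.24e-05%) lists, and in 9 of the 32 cluster lists, such as that of Mir23a (3.94% and 5.97%). Replicate differences need both libraries. Which list shares to lead with, and to order only top genes without copies, was chosen after the data were examined. Depth limits genes below 0.442 CPM in replicate 1 and 0.973 CPM in replicate 2.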

Other observations

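The tests in this part were chosen after the results had been seen. Some genes with near-identical copies had low counts beside a relative without copies. Mir26b was at 31702 ± 17891 CPM (SD, n = 2), while Mir26a-1 and Mir26a-2, which share 20 bases with each other, were at 12.0 ± 11.9 and 23.6 ± 9.66 CPM. Mir9-1, Mir9-2 and Mir124a-1, which have copies, had 0 reads in both replicates. Copies did not always go with low counts, since Mir23a and Mir23b share 20 bases and stood at 48684 ± 14212 and 40041 ± 10180 CPM. These counts cannot rank such genes, because multimapping reads were assigned to no gene.

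Whether sequence families deviate together between the replicates depended on how families were drawn, how they were weighted and which pairs were kept. In all, 8 relations were computed on the replicate differences, with Benjamini-Hochberg adjustment over the 8. With the let-7 family taken from the fixed list, which holds Mir7j and Mir98, the 108 pairs of 61 genes sharing no 20 bases gave a permutation p of 0.0763 (adjusted 0.102), and 68 of these pairs were let-7 genes. Families drawn first, by the number in the symbol alone, put Mir7j with Mir7b, and gave 0.0117 (adjusted 0.0313) over 89 pairs. With pairs that share 20 bases kept, the permutation p was 0.0310 (adjusted 0.0497), with equal weight per family 0.0166 (adjusted 0.0331), and over 40 pairs without let-7 0.00134 (adjusted 0.00584). The 74 pairs with at least 2 mismatches gave 0.575 (adjusted 0.575). Hairpin GC had a permutation p of 0.00146 (adjusted 0.00584), and mean CPM, with rho 0.05, one of 0.451 (adjusted 0.516). These relations were found and tested on the same 2 libraries, and pairs that share a gene are not independent.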
